A study of Mus musculus with 5 samples.

How the data were processed

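Chromatin immunoprecipitation with sequencing (ChIP-seq) was made on MC3T3-E1 cells, a mouse preosteoblast line, after 24 h with parathyroid hormone (PTH, 1 µg per mL) or vehicle. The 5 libraries, 1 per group, were PTH1R with PTH, THR with PTH, input with PTH, PTH1R with vehicle and input with vehicle, where PTH1R is the PTH receptor and THR the thyroid hormone receptor. THR with vehicle was not analysed here. The labels give the antibodies but no replicate, so no p-value between conditions was computed.

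The processing notes of the submitters name genome build mm10, Bowtie2 2.1.0 and MACS 1.4.2 without saying what each did. The deposited fragment files hold 1 line per aligned pair of reads, and 1 column is a whole-number score with the range of a Bowtie2 mapping quality. Nearly all lines carry the minus strand, so each line was taken as 1 fragment from its start to its end. The longest fragment in each library was 500 bp. Whether identical fragments were removed is not given in the sources used here, but identical lines are present in the deposited files. The peak lists of the authors give tags per peak as counts, per the file headers. Fold enrichment is given by the authors as a ratio, and the false discovery rate (FDR) is deposited as a percent. The header of a further deposited column is broken, and its values form a score with a minimum of 40 in the place where MACS writes p on a log scale. Which input each list was called against and the settings used are not given in the sources used here. Fold enrichment, tags and FDR were taken as the authors deposited them and were not recomputed.

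The depth was 12214791 fragments for PTH1R with PTH, 14444823 for THR, 31255516 for input with PTH, 15537854 for PTH1R with vehicle and 19825169 for input with vehicle. Fragments with the same start and end were counted once in the counts called distinct. Counts were scaled by the total of fragments of a library (RPM). Each ChIP was compared with the input of the same treatment. Fragments were placed by their midpoint, which replaced the 100 bp shift chosen before the data were examined, since each line already spans the fragment. Intervals at the 95% level are exact Clopper-Pearson intervals for shares and exact conditional binomial intervals for ratios of counts. Those for ratios of gene ends to flanks and of gene-rich to gene-poor bins use a normal approximation on the log scale. All of these cover counting error only, and repeat copies of a fragment are not independent molecules. Intervals for medians come from order statistics and take regions or genes as independent. A ratio against a count of 0 was computed against a floor of 3 fragments. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

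The comparisons, the gene lists and the rule for named genes were chosen before the data were examined. So were the alternatives, other than those named below as chosen after seeing the data. Overlap of peak lists meant at least 1 bp. It was set beside 100 random placements of the same peak lengths on the same chromosomes, and, chosen after seeing the data, beside placements at positions of input fragments. Regions of high input were those where either input exceeded 5 times its genome mean density or reached 5 RPM or more. The ratio of PTH1R with PTH over PTH1R with vehicle was taken in the union of both lists as log2 of RPM with a pseudocount of 0.5, and regions at least 2-fold apart were counted among those with at least 30 fragments in both libraries together. Windows of 1 kb were called enriched at 20 or more fragments and 4 times the input, after all libraries were thinned to 12214791 fragments. With distinct fragments, libraries were thinned to 5720473 and the minimum was lowered to 9.

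The annotation held was a RefSeq gene table on mm10 without strand or sequence. Transcription start sites could therefore not be told from gene ends, and both ends of 21631 protein-coding genes took their place. A peak was counted at a gene end when its midpoint lay within 1 kb, and for gene lists when it overlapped the 1 kb around an end. The profile took 50 bp bins within 5 kb and compared the mean within 500 bp of an end with that at 4 to 5 kb. Gene list values are medians of log2 of RPM over input near gene ends, with a pseudocount of 0.2, and their percentiles come from 10000 random lists of the same size matched on deciles of the mean signal of all libraries. Counts of members with a peak were set beside random lists matched on gene length. The 13 lists were thyroid hormone targets, thyroid hormone receptors with their partners, PTH receptor signalling, PTH and cAMP response genes, osteoblast genes, factors regulating osteoclasts, the Wnt and BMP pathway, markers of adipocytes, chondrocytes, macrophages with osteoclasts, and muscle, housekeeping genes, and olfactory receptors.

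Genes were named by a fixed rule. For each list, up to 4 members with a peak at an end and the highest fold enrichment were taken, of which 1 is not reported here. For PTH1R, the 10 regions with the highest and the 10 with the lowest ratio of PTH over vehicle were taken, among those with at least 30 fragments, no high input, on chromosomes 1 to 19 or X, and with a gene end within 10 kb of the midpoint. The region took the name of the protein-coding gene with the nearest end. The 10 sites shared by THR and PTH1R with the highest THR fold enrichment were taken in the same way. *Pth1r*, *Thra*, *Thrb*, *Klf9*, *Hr*, *Dio2*, *Tnfsf11*, *Cxcl1*, *Ccl2*, *Runx2*, *Bglap* and *Mmp13* were named in any case. Their ratios over input use fragments near their gene ends.

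Alternatives tried were distinct fragments, a mapping quality of at least 30, a pseudocount of 0.1 RPM for regions and 0.05 RPM for gene ends, scaling by 10 kb bins without peaks, the other input, reciprocal overlap of 50%, summits within 200 bp, fold enrichment of at least 10, FDR of at most 5%, and gene ends within 2 kb. The search for the thyroid hormone response motif was not made because no genome sequence was held, and matching of promoters on CpG content was replaced by the deciles above for the same reason. Strand cross-correlation was not possible because the lines are whole fragments on 1 strand. Exons and introns were not separated because the annotation held gives genes only.

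The methods were tested on simulated data. Of 500 planted overlaps, 500 were recovered in each of the 3 pairs of lists. Each was a copy of a peak moved by less than its length, so full recovery was set in advance and only the counting was checked. Of 200 regions planted at 4-fold, 198 passed the 2-fold rule, and of 200 planted at 2-fold, 53 passed it. False calls numbered 27 and 24, or 0.478% and 0.418% of the other regions with enough fragments. These simulated fragments were independent, without the repeat copies of the libraries, so the rates of false calls do not carry over to the real regions. Of 300 windows planted with a mean count above the rule, 299 were found. A shift of 0.6 on the log2 scale was found in 20 of 20 simulated gene lists, set against random lists without the matching on deciles. Smaller shifts were not tried. A planted gene end ratio of 1.2 was returned as 1.19.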

Results

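The data came from MC3T3-E1 cells, a line of mouse preosteoblasts, given PTH or vehicle for 24 h. Chromatin was precipitated with an antibody against PTH1R in both treatments and with one against THR in PTH cells only, and each treatment had an input. Each of the 5 groups held 1 library, so the differences below have no replicate check. The intervals of shares and ratios cover counting error of these libraries only, and those of medians the spread over regions or genes. The libraries held 12214791 fragments (PTH1R with PTH), 14444823 (THR with PTH), 31255516 (input with PTH), 15537854 (PTH1R with vehicle) and 19825169 (input with vehicle). Distinct fragments numbered 5720473, 8287500, 18952443, 7004418 and 12329069 in the same order, so that repeat copies made up 53.2%, 42.6%, 39.4%, 54.9% and 37.8%. A satellite repeat region on chromosome 2 took between 6.74% and 9.48% of each library. No flow cell was shared between PTH and vehicle libraries, so treatment and sequencing run cannot be told apart.

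Where the PTH receptor and the thyroid hormone receptor were listed on chromatin was asked first. The authors listed 30025 peaks for PTH1R with PTH, 6929 for THR with PTH and 23454 for PTH1R with vehicle. The peaks were small, with a median of 5, 8 and 6 distinct fragments, and 57.9% of the PTH1R peaks with PTH held 5 or fewer. Fold enrichment, the authors' own value, had a median of 7.41, 6.34 and 6.79 in the 3 lists. Peaks with at least 20 distinct fragments, at least 4 times the input and 90% of fragments at a mapping quality of 30 or more numbered 1 for PTH1R with PTH, 2 for THR and 2 for PTH1R with vehicle, a rule chosen after the values were seen. The single such PTH1R peak with PTH lay at chromosome 6, 51602658 to 51604500, and held 21 distinct fragments at 5.35 times the input (95% interval 2.56 to 11.6). The vehicle peaks lay on chromosome 1 at 16258023 to 16259421 and at 12520492 to 12522227. The THR peaks lay at chromosome 6, 32001780 to 32003463, and at chromosome 17, 75915504 to 75916937. At the first, PTH1R was also at least 2-fold over input in both treatments. With PTH it stood there at 3.73 times the input (1.28 to 11.1) on 9 distinct fragments, and at the second at 0.663 times (0.0706 to 3.11) on 2.

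The share of fragments in peaks measured enrichment against the input. Over the whole lists, PTH1R with PTH had 12.2% of its fragments in its own peaks, THR 11.4% and PTH1R with vehicle 3.71%, which were 0.995, 0.971 and 2.45 times the share of their input. The lists held 55, 20 and 36 peaks of high input. Without them, PTH1R with PTH had 3.84% in its peaks (Clopper-Pearson interval 3.83 to 3.85), 6.13 times the input share of 0.627%. THR had 0.855% (0.851 to 0.860), 4.66 times its input, and PTH1R with vehicle 2.67% (2.66 to 2.68), 5.55 times its input. Among distinct fragments these ratios were 4.08, 3.36 and 3.81. The peaks were listed from these same ChIP libraries, so the ratios are not an independent measure of enrichment.

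Whether PTH moved the receptor to other sites was asked by comparing PTH1R peaks between PTH and vehicle. Of the 30025 peaks with PTH, 528 overlapped a vehicle peak, or 1.76% (1.61 to 1.91). Random placements of the same lengths gave a mean of 415 overlaps (range 364 to 481), and placements at distinct input fragments gave 473 (420 to 531), with 1 of 100 as high as the lists. Placements at all input fragments, which fall often in the repeats of high input, gave 640. In the regions listed with PTH only, PTH1R with vehicle lay at a median log2 of -0.02 over its input, and in those listed with vehicle only, PTH1R with PTH lay at -0.06. In the 509 regions of both lists outside high input, the medians were 1.14 with PTH and 1.08 with vehicle. Over the 52949 regions of either list, the median log2 ratio of PTH over vehicle was 0.72 (0.70 to 0.74). More of these regions were listed with PTH only (29497) than with vehicle only (22927), which by itself favours a positive median. At the ends of all genes the median was 0.17, but those were not chosen by peaks and had a pseudocount of 0.2, so the 2 medians are not like measures. Of the 4295 regions with at least 30 fragments, 1075 (25.03%) were at least 2-fold higher with PTH and 892 (20.8%) at least 2-fold lower. Counting distinct fragments left 290 such regions, 29 higher (10.0%) and 33 lower (11.4%). A region listed in 1 library was chosen for its count there, so a difference from the other library is built into these ratios.

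**Figure D1:**
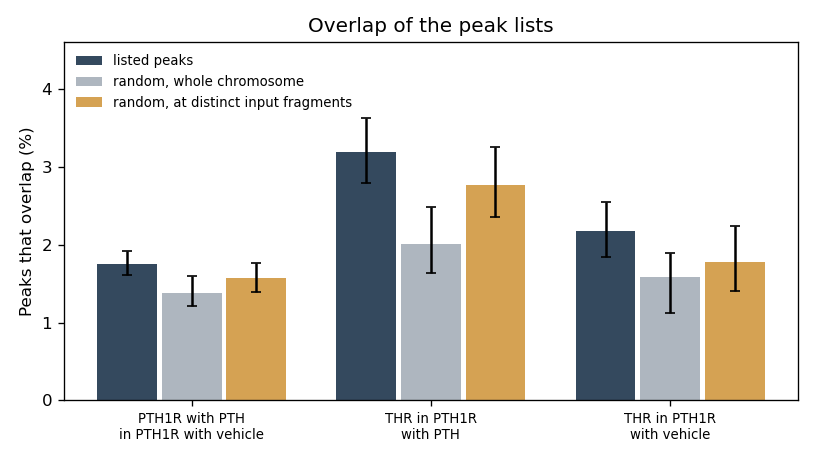
Share of peaks (%) of the list named above that overlap the list named below, for the listed peaks with Clopper-Pearson 95% intervals and for 100 random placements on the whole chromosome or at distinct input fragments, with bars at the mean and whiskers over the range. The listed shares were 1.76%, 3.19% and 2.18%.

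At the gene *Prrc2c* the PTH1R signal was the most shifted toward PTH. The region at chromosome 1, 162671809 to 162673278, held 110 fragments with PTH and 0 with vehicle, at least 46.6-fold higher against a floor of 3 fragments (95% lower limit 37.3), or at least 24.1-fold with distinct fragments (18.98), and 2.73% of the fragments with PTH had a mapping quality of 30 or more. *Gabra6* (chromosome 11, 42303041 to 42304063) had 152 against 13 fragments, 14.9-fold higher (8.44 to 28.6), 2374 bp outside the gene and with 2.63% at that mapping quality. *Cyp20a1* had 50 against 0, at least 21.2-fold higher (lower limit 16.6), with 4.0% at that quality, and *Ubqln5* 82 against 6, 17.4-fold (7.65 to 48.75), with none. The regions at *Pde4dip*, *Cldn2* and *Ccdc65* each held 0 fragments with vehicle and were at least 14.4, 14.4 and 12.7-fold higher, or at least 4.898, 2.86 and 2.45-fold by 12, 7 and 6 distinct fragments. The 95% lower limits of their ratios, which use no floor, were 11.1, 11.1 and 9.72, and 3.40, 1.76 and 1.44 with distinct fragments. *Pla2g12a* was 41.98-fold higher (7.03 to 1708), *Kctd17* 23.5-fold (6.07 to 201.5) and *Zfr2* 40.7-fold (6.8 to 1657), on 10, 12 and 7 distinct fragments. By distinct fragments, these 3 ratios were 12.2 (1.74 to 531.4), 7.35 (1.64 to 67.6) and 8.57 (1.1 to 386.3). None of the ratios of these regions was divided by input. In RPM, input with PTH was above input with vehicle at *Prrc2c*, *Gabra6*, *Ubqln5*, *Pla2g12a*, *Kctd17* and *Zfr2*. It was below at *Cyp20a1*, *Pde4dip*, *Cldn2* and *Ccdc65*. The values were 0.352 against 0.0504 at *Pla2g12a* and 0.192 against 0.706 at *Cldn2*.

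In the other direction, *Esyt1* (chromosome 10, 128524761 to 128525862) held 0 fragments with PTH and 39 with vehicle, at most 0.0979 times the vehicle level against the same floor (95% upper limit 0.126), or 0.306 with distinct fragments (0.441). *Rcc2* (0 against 37), *4930447A16Rik* (0 against 35), *Fcnb*, *Srsf10*, *Polr2k* and *BC051142* (0 against 31 each) had no fragment with PTH. Against the floor, *Rcc2* reached at most 0.103 (95% upper limit 0.133) and *4930447A16Rik* 0.109 (0.141) times the vehicle level, and the remaining 4 reached 0.123 (0.161). By distinct fragments, the 0 with PTH stood against 5 for *Rcc2* and 6 for *4930447A16Rik*, with upper limits of 1.34 and 1.04, so no decrease is shown there. With 9 for *Srsf10* and 11 each for *Fcnb*, *Polr2k* and *BC051142*, the upper limits were 0.620 and 0.488. *Astl* had 1 against 38 fragments, a ratio of 0.0335 (0.000826 to 0.198), and *Fbrs* 1 against 37, a ratio of 0.0344 (0.000848 to 0.204). With distinct fragments these ratios were 0.0765 (0.0018 to 0.493) and 0.111 (0.00259 to 0.766). The region nearest *Cilk1* (chromosome 9, 78175276 to 78175684) lay 3162 bp outside that gene and held *Rn7sk*, the gene of the small nuclear RNA 7SK, which binds a regulator of transcription elongation. It had 3 fragments with PTH and 53 with vehicle, a ratio of 0.0720 (0.0144 to 0.222), and 0.0628 (0.00735 to 0.243) with distinct fragments. The ratios in this direction were not divided by input either. In RPM, input with PTH was below input with vehicle at *Esyt1*, *Rcc2*, *Srsf10*, *Polr2k* and *Fbrs*. It was above at *4930447A16Rik*, *Cilk1*, *Astl*, *Fcnb* and *BC051142*. The values were 0.160 against 0.706 at *Fbrs* and 0.480 against 0.151 at *Fcnb*. The 20 regions named for PTH1R are the extremes of 1217 eligible ones, and such extremes exceed their true ratios.

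**Figure D2:**
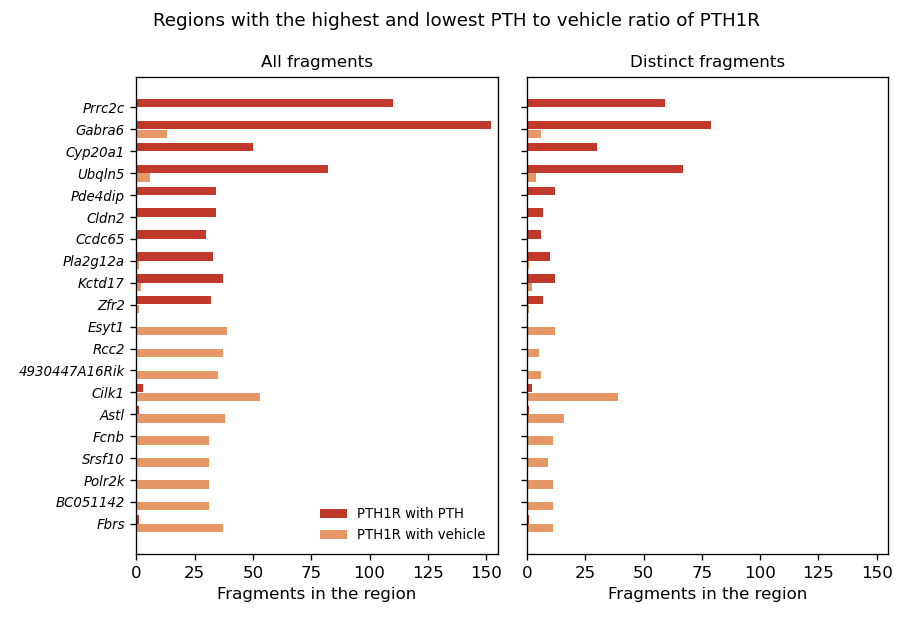
Fragments of PTH1R with PTH and with vehicle in the 10 regions with the highest and the 10 with the lowest ratio, counted over all fragments (left) and over distinct fragments (right), each region named by the nearest gene end. *Prrc2c* held 110 fragments with PTH and 0 with vehicle, and *Esyt1* 0 and 39.

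Whether THR sat at the same places as PTH1R in PTH cells was asked next. Of the 6929 THR peaks, 221 overlapped a PTH1R peak with PTH, or 3.19% (2.79 to 3.63), against a mean of 139 for random placements (113 to 172) and 192 at distinct input fragments (163 to 226), with 2 of 100 as high. With the vehicle PTH1R list, 151 overlapped, or 2.18% (1.85 to 2.55), against 109 (78 to 131) and 124 at distinct input fragments, again with 2 of 100 as high. Placements at all input fragments gave 453 and 156. Lists called against the same input can overlap through it, which none of these placements takes into account. Outside high input, THR lay at a median log2 of 0.02 over input and 1.19 times the input in pooled fragments in PTH1R peaks listed with PTH only, at -0.02 and 1.07 in those listed with vehicle only, and at 0.05 and 1.32 in regions of both lists. With the regions of high input kept, the pooled values for PTH only and for both lists turned below input, to 0.929 and 0.915. In THR peaks, PTH1R lay at a median log2 of 0.01 with PTH and -0.05 with vehicle. With libraries scaled to their fragments outside high input, the pooled value of THR in the regions listed with PTH only was 1.17, that of PTH1R with vehicle over the same input 1.16, and THR over the input with vehicle 1.04 (1.03 to 1.04).

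Among the 68 of 208 sites shared by THR and PTH1R with a gene end within 10 kb, *Ttc21b*, a gene of cilium transport, had the highest THR fold enrichment. Its site (chromosome 2, 66189109 to 66189639) had a fold enrichment of 10.36 for THR and held 51 THR fragments, 4.6 times the input (2.78 to 7.81), with none at a mapping quality of 30 or more. *Ttc21b* was also in the vehicle list. *Pcbp1* and *Cacnb1* had a fold enrichment of 9.31, *Ptcra* of 9.25, *Tmem132c*, *Tmem235* and *Fpr-rs4* of 8.07, *Prkca* of 7.59, and *Rnf220* and *Lrguk* of 7.45. Those 9 sites were not in the vehicle list and held 6 to 13 distinct THR fragments. For PTH1R the interval of distinct fragments over input included 1 at 8 of these 9 sites, all but *Ptcra*, so that sharing rests there on the peak lists. At *Prkca* (chromosome 11, 107936865 to 107937712), which encodes a kinase downstream of Gq-coupled receptors, THR lay at 5.53 times the input (2.46 to 13.6), or 4.57 (1.42 to 17.0) with distinct fragments. At *Ptcra* and *Fpr-rs4* the intervals of distinct fragments included 1.

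Windows measured enrichment without the peak lists, at an equal total of fragments but with shares of repeat copies that differed between libraries. At 12214791 fragments per library, 5493 windows of 1 kb were enriched for PTH1R with PTH, 757 for THR and 2480 for PTH1R with vehicle, while the inputs set against each other gave 90 and 179. PTH1R with PTH and with vehicle shared 12 windows, against 6.74 expected from the number of enriched windows on each chromosome. THR and PTH1R with vehicle shared 2, against 0.939. PTH1R with PTH and THR shared 22, against 2.03, but both were set against the same input, which that number does not take into account. With distinct fragments, thinned to 5720473 and with the minimum lowered to 9 fragments, the counts were 2802, 1816 and 2549, and 1476 and 1480 for the inputs.

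**Figure D3:**
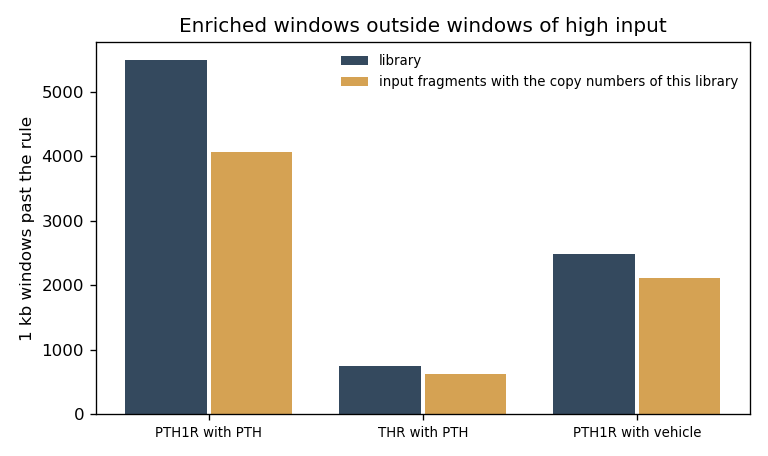
Number of enriched 1 kb windows outside windows of high input, for each ChIP library and for input fragments given the copy numbers of that library. The libraries had 5493, 743 and 2480 windows and the copied input 4065, 622 and 2119.

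Whether binding lay near genes was asked with gene ends. PTH1R peaks with PTH lay within 1 kb of an end in 1676 cases, 5.58% (5.33 to 5.85), 1.71 times the random share of 3.27%. Vehicle PTH1R peaks did so in 850 cases, 3.62% (3.39 to 3.87), 1.12 times random. THR peaks did so in 197 cases, 2.85% (2.47 to 3.26), against 3.24% (2.83 to 3.68) at random. Away from ends, 42.3% of PTH1R peaks with PTH, 38.3% of THR peaks and 41.2% of vehicle PTH1R peaks lay in genes. In the profile, PTH1R with PTH was 1.09 times as high at ends as in the flanks (1.08 to 1.09), above 1 on 20 of 20 chromosomes and 1.13 times the input ratio. THR stood at 0.937, PTH1R with vehicle at 0.969 and the inputs at 0.960 and 0.965. With distinct fragments the PTH1R value with PTH was 1.06.

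**Figure D4:**
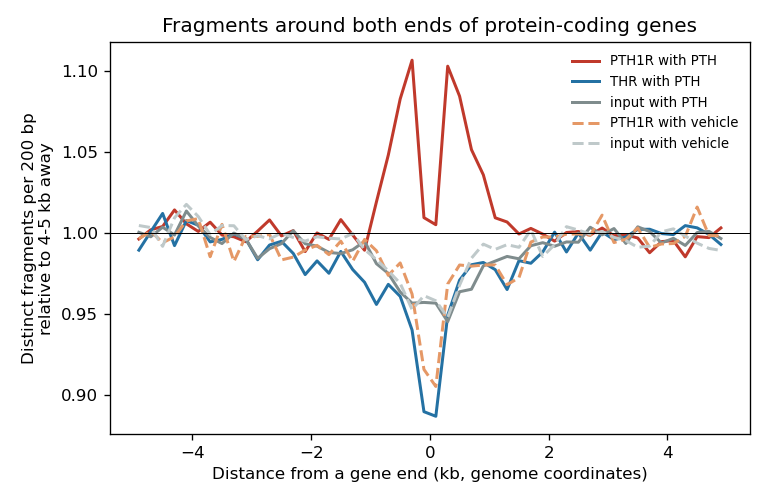
Mean density of distinct fragments per 200 bp around both ends of protein-coding genes, relative to that at 4 to 5 kb, by distance in kb, for the 5 libraries. PTH1R with PTH rose above 1 within about 1 kb of the ends, and the other 4 libraries fell below 1 there.

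The genes of thyroid hormone and PTH action were then compared with other lists, as medians of log2 over input near gene ends. Thyroid hormone targets stood at 0.34 for PTH1R with PTH (percentile 62.6 of random lists), -0.04 for THR (41.8) and 0.38 for PTH1R with vehicle (98.0). Thyroid hormone receptors and partners stood at 0.41 (81.7), 0.05 (66.6) and 0.17 (80.01). PTH receptor signalling genes stood at 0.50 (88.1), -0.15 (12.9) and -0.22 (5.30), and their log2 ratio of PTH over vehicle was 0.61 (98.2). PTH and cAMP response genes stood at 0.28 (59.6), -0.25 (4.02) and -0.12 (16.7). Of the same lists, receptors and partners had a log2 ratio of PTH over vehicle of 0.55 (97.1), thyroid hormone targets 0.28 (67.2) and PTH and cAMP response genes 0.25 (67.5). The medians of all genes were 0.26, -0.01 and 0.03. Over 13 lists and 4 measures, some percentiles this far out arise by chance. Across the alternatives of processing, the ratio of PTH over vehicle ranged from 0.12 to 0.58 for receptors and partners, from -0.09 to 0.31 for thyroid hormone targets, from 0.06 to 0.27 for PTH and cAMP response genes and from 0.36 to 0.67 for PTH receptor signalling, and the sign turned for THR at thyroid hormone targets and for PTH1R with vehicle at PTH and cAMP response genes.

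Osteoblast genes stood at 0.25 (33.4) for PTH1R with PTH, 0.25 (95.9) for THR and 0.02 (40.9) for PTH1R with vehicle. The Wnt and BMP pathway stood at 0.45 (92.4), 0.26 (98.4) and 0.40 (99.3). Across the alternatives the THR medians ranged from -0.02 to 0.29 for the Wnt and BMP pathway and from -0.08 to 0.31 for osteoblast genes. Factors regulating osteoclasts stood at -0.02 (3.22), -0.08 (29.2) and -0.10 (18.4). Adipocyte markers stood at 0.11, -0.08 and 0.10, chondrocyte markers at 0.26, 0.00 and -0.13, macrophage and osteoclast markers at -0.01, 0.10 and 0.24, and muscle markers at 0.00, -0.28 and -0.21, with percentiles between 7.70 and 77.1. Housekeeping genes stood at 0.44 (76.3), -0.11 (15.8) and -0.13 (10.6), with a ratio of PTH over vehicle of 0.53 (96.4). The ratio of PTH over vehicle was -0.08 (6.56) for osteoblast genes, and in the remaining 7 lists its percentiles lay between 0.13 (olfactory receptors) and 75.6 (muscle markers). The 1110 olfactory receptor genes, silent in most tissues, stood at -0.09 (percentile 0) for PTH1R with PTH, -0.02 (88.2) for THR and -0.08 (0.01) for PTH1R with vehicle.

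Peaks at gene ends named a few members of each list. PTH receptor signalling had 6 members with a PTH1R peak with PTH, where random lists of like gene lengths had a mean of 2.06 (95% of lists 0 to 5), and 2 with a vehicle peak. Counted in the gene or within 1 kb, 13 members had a PTH1R peak with PTH, within the range of random lists (6 to 14), and with 13 lists in 3 libraries 1 count above its range can arise by chance. The examples were *Gnaq* (fold enrichment 8.73), *Plcb1* (7.44) and *Atf4* (6.59) with PTH and *Arrb2* (6.79) with vehicle, on 3 to 7 distinct fragments. *Ncor1*, a thyroid hormone receptor corepressor, had a PTH1R peak with PTH at chromosome 11, 62457468 to 62458474, with a fold enrichment of 9.06 and 10 distinct fragments. In the same list *Ncoa3* (8.23) and *Ncoa2* (4.39) had a peak with PTH and *Rxrb* (8.67) with vehicle. Thyroid hormone targets had *Gpd2* (8.23) and *Cpt1a* (7.67) with PTH. Among PTH and cAMP response genes, *Il6* (8.23), *Crem* (7.41) and *Ptgs2* (7.41) had peaks with PTH. Receptors and partners had 3 such members with PTH against a random mean of 2.1, targets 2 against 2.06 and response genes 3 against 2.55. Osteoblast genes had *Postn* (9.51), *Spp1* (9.51) and *Dlx3* (7.47) with vehicle and *Dlx5* (9.06) with PTH. Among factors regulating osteoclasts, *Il6* and *Sema3a* (8.23 each) had peaks with PTH and *Efnb2* (5.43) with vehicle. The Wnt and BMP pathway had *Lef1* (8.83) and *Tcf7* (8.76) with vehicle and *Grem1* (6.31) and *Wnt3a* (5.76) with PTH. With PTH, that pathway and the factors regulating osteoclasts each had 2 members, against random means of 2.49 and 2.16. With vehicle, the pathway had 4 against 1.42 (0 to 4) and osteoblast genes 3 against 1.12 (0 to 3). Outside PTH receptor signalling and olfactory receptors, every count at gene ends lay within its random range. *Ihh* (6.11), *Adgre1* (8.15) and *Ptprc* (7.47) had vehicle peaks, and no adipocyte or muscle marker had any. Of housekeeping genes, *Rps3* (9.88) and *Actb* (6.86) had PTH1R peaks with PTH and *Tbp* (6.15) a THR peak. Olfactory receptors, by far the longest list, had 52 members with a PTH1R peak with PTH, where random lists had a mean of 67.4 (53 to 83), and their examples were *Olfr1104* (14.82), *Olfr222* (13.17) and *Olfr59* (13.17) with PTH and *Olfr1* (11.55) with vehicle. THR peaks at gene ends were too few for these lists, with a mean of 0.247 members in random lists the size of the thyroid hormone targets, which had 0. In the gene or within 1 kb, 4 thyroid hormone targets had a THR peak (*Me1*, *Rcan2*, *Cpt1a* and *Ppargc1a*, named after the values were seen), against a mean of 2.94 (0 to 6) in random lists.

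The ratios for the genes named in any case use fragments near their gene ends, not over the whole gene. *Hr*, a thyroid hormone response gene, was the 1 of these 12 genes whose distinct fragments excluded the input level. Near its ends PTH1R with PTH lay at 3.41 times the input (1.66 to 7.16), and at 3.73 (1.28 to 11.1) on 9 distinct fragments. Over the other input it lay at 1.71 (0.866 to 3.38). At *Hr*, THR stood at 1.44 (0.580 to 3.43) and PTH1R with vehicle at 1.01 (0.476 to 2.09), and over the other input at 0.722 (0.300 to 1.63) and 2.01 (0.916 to 4.42), so the order of PTH and vehicle at *Hr* depends on the input used. Over all fragments, *Bglap* at 4.37 (1.83 to 12.0) and *Thra* at 1.69 (1.03 to 2.78) lay above input for PTH1R with vehicle, and *Klf9* at 0.473 (0.268 to 0.802) and *Mmp13* at 0.309 (0.123 to 0.683) below. *Cxcl1* lay below for PTH1R with PTH, at 0.357 (0.124 to 0.842), and *Ccl2* for THR, at 0.490 (0.238 to 0.929), and with distinct fragments the intervals of these 6 values included 1. Over the other input, *Ccl2* for THR and *Mmp13* for PTH1R with vehicle stayed below input, while the other 4 intervals included 1 and *Bglap* fell to 1.46 (0.827 to 2.55). *Bglap* stood above the other input for PTH1R with PTH, at 3.71 (1.44 to 10.7), and for THR, at 4.51 (1.87 to 12.4). With 36 intervals read, some exclude 1 by chance. *Pth1r*, *Thrb*, *Dio2*, *Tnfsf11* and *Runx2* had intervals that included 1 in the 3 ChIP libraries, except *Dio2* for PTH1R with vehicle over the other input, at 2.01 (1.03 to 3.94). THR had 0 peaks in or within 1 kb of the 12 genes. PTH1R had peaks at 5 of them with PTH (*Pth1r*, *Thra*, *Thrb*, *Hr* and *Runx2*) and at 4 with vehicle (*Thra*, *Thrb*, *Hr* and *Runx2*). Such a peak was common, since 34.5% of all protein-coding genes had one with PTH and 27.3% with vehicle, against 9.53% for THR. The PTH1R peaks at *Pth1r*, *Thra*, *Thrb*, *Hr* and *Runx2* lay more than 1 kb from a gene end, so the ratios above do not measure them.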

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

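Of the tests in this part, those of the gene ends that weigh sequencing lane, fragment length and base composition were written down before their results were seen, and the comparison of gene-rich regions between the ChIP libraries was chosen after.

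The ratio of gene ends to flanks drew attention because PTH1R stood above 1 with PTH, at 1.09, and below 1 with vehicle, at 0.969. The inputs also stood below 1, at 0.960 and 0.965, so that PTH1R was 1.13 times its input with PTH and at the input level with vehicle (1.004 times). The difference between the treatments was not tested, since each group had 1 library. The 18S ribosomal RNA locus *Rn18s-rs5* (chromosome 17, 39846354 to 39848202), outside the protein-coding genes compared, drew attention with 2.23 times the input for PTH1R with PTH (1.98 to 2.51) and 2.34 times for PTH1R with vehicle (2.07 to 2.64), from distinct fragments, and this difference from input was not tested against replicates. By all fragments, the run of high input that holds it lay at 2.52 times the input for PTH1R with PTH, 1.38 for PTH1R with vehicle and 0.779 for THR. By distinct fragments, 10 of 24 such runs lay at 1.5 times the input or more for PTH1R with PTH, and 1 for PTH1R with vehicle. The run with *Rn18s-rs5*, annotated as a pseudogene, lay at 2.22 with PTH and 1.49 with vehicle. The 1 run with vehicle was another, at chromosome 17, 13549001 to 13554000 (1.71). The satellite run on chromosome 2 lay at 2.36 with PTH by distinct fragments but at 0.711 by all, so distinct fragments alone do not set the 18S locus apart with PTH.

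The rise of PTH1R with PTH at gene ends is not explained by the lane, since THR fragments of the lane shared with that library lay at 0.970 times the input (0.959 to 0.982), nor by fragment length, since 99.3% of the excess stayed when input fragments were weighted to the lengths of PTH1R. A property of gene-rich regions favoured by the library, such as base composition, may contribute. Away from genes, PTH1R with PTH over input was 1.18 times as high in gene-rich as in gene-poor bins (1.18 to 1.19). The same ratio was 1.11 for PTH1R with vehicle and 1.06 for THR, which had no rise at gene ends over input, so such a property may not be the whole account. Base composition was not measured, and the bins cannot tell it from other properties of gene-rich regions, binding among them. The base composition of the ends themselves and binding at active genes cannot be told apart, as both would raise housekeeping over olfactory receptor ends, where the difference was 0.428 (1.48 against 1.051 times the input), and no genome sequence was held to separate them. A change of PTH1R by the PTH treatment stays open and untested, as does a difference between the sequencing runs of the treatments.

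Tests of repeat copies, of low mapping quality and of a few genes with many fragments at gene ends were also run and left the excess in place, at 1.11 times the input with distinct fragments, 1.14 with a mapping quality of at least 30, and 99.5% of the excess without the 1% of ends with the most fragments.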

How the results depend on the processing

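Chosen after seeing the data were the settings of at least 10 distinct fragments per peak, a mapping quality of at least 30, the other input for THR in PTH1R peaks, both settings of the genes named in any case, and gene ends without the top 1%. Outside the gene lists, 23 results gave 105 values under alternatives. Of these, 48 stayed within the interval of the main value (counts within 1.5 times) and 57 moved. Reversals numbered 0, where a change of sign counted only if the interval of the main value excluded no difference. Counts and shares could not be labelled as reversed under this rule. The 0 therefore does not speak to the order of libraries or directions, which changed in some settings below. Of 195 values of 52 gene list medians, 187 stayed within their wide intervals and 8 moved, but 23 of the 52 medians took the other sign under at least 1 alternative. For the genes named in any case, 3 of 72 values moved, all at *Bglap* over the other input (3.71, 4.51 and 1.46 times). For the values below, given for PTH1R with PTH, THR and PTH1R with vehicle in that order where there are 3, the cause was not tested unless stated. No paired analysis was possible because each group had 1 library, and the peaks held a median of only 5, 8 and 6 distinct fragments.

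With a fold enrichment of at least 10, the lists held 1753, 65 and 652 peaks, and the overlaps of PTH1R with vehicle PTH1R, of THR with PTH1R under PTH and of THR with vehicle PTH1R were 0.171%, 6.15% and 4.62%. With at least 10 distinct fragments the lists held 1218, 1520 and 1603 peaks, so PTH1R with PTH went from the longest list to the shortest. With reciprocal overlap of 50% the 3 overlaps were 0.819%, 1.47% and 1.11%, and with summits within 200 bp 0.639%, 1.198% and 0.981%, since these ask for closer peaks. With equal numbers of top peaks the THR overlaps were 0.924% and 0.866%, as fewer PTH1R peaks were used. These were 64 and 60 peaks, against means of 33.8 and 33.7 for random placements on the whole chromosome.

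The share of fragments in own peaks was 5.67%, 2.85% and 2.43% with distinct fragments, 3.89%, 9.23% and 3.28% at an FDR of at most 5%, and 3.84%, 0.855% and 2.67% without high input, the last because peaks of many repeat fragments were left out. The median log2 ratio of PTH over vehicle was 0.38 with distinct fragments, 1.04 with a pseudocount of 0.1 RPM, 0.64 with fragments placed by their 5′ end, 0.65 after division by input and 0.66 at a mapping quality of at least 30. Regions 2-fold higher and lower numbered 29 and 33 of 290 (10.0% and 11.4%) with distinct fragments, and 22257 and 15258 with no minimum. The main setting gave 1075 and 892, so their order turned with distinct fragments.

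The median log2 of THR over input in PTH1R peaks listed with PTH only was 0.0356 with distinct fragments and 0.0233 after scaling by bins without peaks. It was 0.0648 with a pseudocount of 0.1 and 0.00 over the other input. In regions of both PTH1R lists the median log2 was 0.14 over the other input. Enriched windows numbered 2802 for PTH1R with PTH and 1816 for THR with distinct fragments, a setting that also lowered the depth to 5720473 and the minimum to 9 fragments, and 1944, 194 and 846 at 8 times the input.

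Peaks at gene ends within 2 kb were 9.20%, 5.27% and 6.89%, since the span is wider. The ratio of gene ends to flanks was 1.06, 0.927 and 0.947 with distinct fragments, 1.03, 0.929 and 0.944 without ends that held a peak, and 1.06, 0.914 and 0.944 without the top 1% of ends. Among gene lists, THR over the other input stood at -0.19 for thyroid hormone targets, -0.23 for PTH receptor signalling, -0.41 for factors regulating osteoclasts and 0.04 for olfactory receptors. The olfactory list stood at -0.19 (distinct fragments) and -0.15 (2 kb) for PTH1R with PTH, -0.06 for THR and -0.05 for PTH over vehicle (distinct fragments).

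The alternatives for the motif and for strand cross-correlation were not run, as explained with the processing.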

Other observations

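Of the tests in this part, all those of the windows were chosen after the result was seen, as were the tests of passed fragments and of shared binding for THR in PTH1R peaks, while the test of the input assumed to have been used to list the peaks was written before.

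*Rn7sk*, which encodes the RNA 7SK (chromosome 9, 78175302 to 78175633), was the noncoding gene that stood out most with vehicle. Chosen after its values were seen among 14342 noncoding genes, it held 39 distinct PTH1R fragments with vehicle and 0 in the vehicle input, at least 22.9-fold higher against a floor of 3 (95% lower limit 17.7). It held 2 distinct PTH1R fragments with PTH and 0 of THR. The pseudogene *Gm13456*, chosen in the same way, held 27 distinct fragments with vehicle against 3 in input, 15.8-fold higher (4.87 to 81.6).

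Mitochondrial DNA took 0.0129% of PTH1R with PTH, 0.0142% of THR and 0.0183% of PTH1R with vehicle, against 0.244% and 0.241% of the inputs. Fragments of chromosome X lay at 0.519 to 0.568 of the median autosome density in the 5 libraries, and those of the autosomes between 0.648 (chromosome 13) and 1.48 (chromosome 19).

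The enriched windows may come in large part from repeat copies. Input fragments given the copy numbers of each ChIP passed the same rule in 74.0% as many windows as PTH1R with PTH, 83.7% as many as THR and 85.4% as many as PTH1R with vehicle. The source of the copies, PCR or other, was not tested. On chromosome 19, 37.5%, 53.0% and 29.5% of the repeat copies of these libraries lay within 2500 flow cell units of another copy. For the inputs these shares were 60.3% with PTH and 46.9% with vehicle. Local binding stays open for the remainder, since distinct fragments held out of the choice of windows lay at 1.56 times the input (1.47 to 1.67) for PTH1R with PTH, 1.79 (1.63 to 1.957) for THR and 1.27 (1.21 to 1.34) for PTH1R with vehicle, under the bound of 2 set for binding. Those values use windows with at least 20 fragments (553, 151 and 1019 windows), a minimum raised from 10 after the first result. At 10 fragments (35283, 20119 and 46992 windows, many more than the 5493, 743 and 2480 weighed) they were 1.13, 1.06 and 1.08, under the bound set against binding, so the choice of minimum decides whether binding is argued against. Windows of high input were also left out of the copy test after its first result, because their repeat copies arise from many genome copies.

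The excess of THR over input with PTH in PTH1R peaks listed with PTH only, 1.17 in pooled fragments scaled to those outside high input, is not explained by fragments passed between libraries of a lane, since 99.8% of it stayed without identical fragments. Shared binding is argued against as its main source, since THR of the lane without PTH1R lay at 1.03 times the input with vehicle (1.017 to 1.04). If the input with PTH was used to list the peaks, which the sources used here do not state, its low counts there may account for most of the excess, since THR lay at 1.04 times the input with vehicle there (1.03 to 1.04), and PTH1R with vehicle, from other cells, at 1.16 times the input with PTH and 1.021 times its own. The tests first written gave other readings and were replaced on the assumption that this input had served to list the peaks: THR of the lane without PTH1R lay at 1.19 times the input of its lane, which met the bound set for shared binding, and fragments identical to PTH1R were 4.96 times as frequent in the shared lane as in the other (4.2 to 5.89). A small shared part and a difference made by the treatment (THR with vehicle was not analysed here) stay open and untested.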
